A study of Mus musculus with 273 samples.

How the data were processed

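Small RNA was sequenced from right cortex, right striatum, hypothalamus and liver of male wild-type C57BL/6J mice aged 26 weeks, an inbred laboratory strain, collected every 3 h over 36 h. Per the labels, total RNA was extracted with a column kit that retains small RNA, its quality was read on a Bioanalyzer, small RNA was enriched, and libraries followed the Illumina protocol. The deposited tables hold whole-number counts that the authors made for each library and each miRNA hairpin, with no normalization. The submitters' processing notes name STAR 2.7.3a, HTSeq 0.10.0 and the GRCm38 (mm10) build. They do not state the trimming, the miRBase release or the handling of reads that match several places. A hairpin count adds both mature arms, so the arms cannot be separated here, and 153 features share their name with another genomic copy of the same miRNA, whose counts depend on how such reads were treated. Of the 1226 hairpins in the tables, 222 had no count in any library. Positions came from the RefSeq annotation of GRCm38.p6, which placed 1209 of the hairpins; miR-7a-1, miR-7a-2, miR-92a-1 and miR-146a had no single match and are given without a position.

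Total counts ran from 1164449 to 4980887 per library in cortex, from 26341 to 4022070 in striatum, from 1079380 to 3954710 in hypothalamus and from 1988671 to 5236177 in liver. The lowest striatum total belonged to ZT9 replicate 6, and the next lowest was 743902. A count of 0 allows up to 3 counts, which is 0.602 to 2.58 CPM (counts scaled to a common library total) in cortex, 0.759 to 2.78 in hypothalamus, 0.573 to 1.51 in liver and 0.746 to 113.9 in striatum. These limits cover counting error only, since reads carried no molecular identifiers. Each of the 273 libraries was mapped to its tissue and time point from its label, with none left over. Zeitgeber time (ZT) was the time point modulo 24 h. By convention ZT0 is lights on, but the lighting schedule was not stated in the labels used here. This gave 31 groups of tissue and ZT with 2 to 12 libraries each. Library runs were taken as stretches of consecutive library numbers with 1 L code in the labels, which gave 14 runs; the meaning of that code was not stated. Liver libraries fell in 5 of these runs and brain libraries in 10, with 1 run shared through 1 hypothalamus library. A fit with run as a term separates liver from brain through that library alone.

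Tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr and quasi-likelihood F tests, and adjusted p-values follow Benjamini and Hochberg, with 0.05 as the threshold. Rhythm was tested in each tissue with a cosine and a sine of period 24 h. Its size is the peak-to-trough log2 ratio of that curve, and its phase is the peak ZT, both with standard errors (SE). The difference in rhythm between a pair of tissues was the test of the interaction of these terms with tissue. Tissues were compared in 1 fit of all libraries with ZT as a factor, and a call also needed an absolute log2 ratio of at least 1. Passages were compared at ZT0 to ZT12, which the series covers at 0 to 12 h and again at 24 to 36 h, with ZT as a factor. Log2 tissue ratios printed with an SE are coefficients without shrinkage; those printed for other scalings carry the edgeR prior count. Lists were tested with Fisher's exact test, two-sided, for rhythm and passage and with camera on voom values (limma 3.58.1) at a preset correlation of 0.01 for tissue, and again with an estimated correlation. Counts of called features shared by a pair of tissues were tested with Fisher's exact test. Mean CPM values are given with the SD over libraries. DESeq2 1.42.0 served as the other tool for counts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 read the tables and drew the plots. Permutation tests ran in R.

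The groups, tests, alternatives, lists and the rule for naming miRNAs were set before the data were examined. The rule named the 5 most abundant miRNAs of each tissue. For rhythm it named called miRNAs with mean CPM of at least 10 and the largest ratios, those called in most tissues, and every tested clock-linked miRNA. Only some of the clock-linked miRNAs are given below with their values. For tissues the rule named the 6 with the largest smallest ratio among those called against all 3 other tissues with mean CPM of at least 100, and the 3 most abundant members of each list. For rhythm differences it named those with the 5 smallest adjusted p-values with mean CPM of at least 10 in both tissues, and for passages the 5 largest ratios with mean CPM of at least 10. Of the miRNAs in the liver rhythm account, miR-26a-2 and miR-23b fall outside the rule, as do the markers of single libraries. In the rhythm differences miR-29b-1, miR-122, miR-376b and miR-379 fall outside it, each with a mean under 10 CPM in at least 1 tissue of a pair. All of these were chosen after their values were seen. The 20 lists were liver-enriched, neuronal, oligodendrocyte, neuroendocrine, choroid plexus, erythroid, immune, endothelial and muscle or mural cell miRNAs, the miR-200 family, the miR-183 cluster, the miRNAs of the Hox clusters, the Dlk1-Dio3 imprinted cluster on chromosome 12, the Sfmbt2 cluster, the let-7, miR-17/92, miR-29, miR-30 and miR-34 with miR-449 families, and miRNAs linked to the clock in the literature. The lists overlap.

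Alternatives were DESeq2 size factors or library totals in place of TMM, DESeq2 and limma voom in place of edgeR, no filter on low counts or mean CPM of at least 10, a 12 h harmonic, ZT as a factor, a linear time term, library run as a term, no ZT term, adjusted p without the ratio minimum, miR-122 left out, parts of the series alone, a block for the title number or for the animal code, and each library left out in turn. Fits without 8 libraries that stood apart from their tissue, passages with the log2 library total as a term, tissues with library run as a term, the animal block with CR88 read as CRM88, and each library left out in turn for all rhythm differences were added after the data were seen. The tests were checked on simulated data made from the deposited counts with known ratios put in. At a ratio of 1.5 the rhythm test recovered 92.4% of the altered features in cortex, 40.3% in striatum, 82.1% in hypothalamus and 89.6% in liver. At a ratio of 2 the rhythm difference test recovered 46.0% to 93.8% in the pairs of tissues. Many features were altered at once in each simulation. At the ratio of 1.5 alone they were 66 of 387 in cortex and 67 of 243 in liver. Counts were drawn for each miRNA on its own, without library run. A threshold on adjusted p is easier to pass when many features change, so these rates may overstate recovery where few miRNAs are rhythmic. The labels carry 79 animal codes, 42 of them in all 4 tissues, 32 in 3, 4 in 2 and 1 in 1, so the tissues came from shared animals. The code CR88 of 1 striatum library was kept apart from CRM88 of the same time point in the other tissues. Read as the same animal they give 78 codes, 43 in all 4 tissues, 31 in 3 and 4 in 2. Profiles taken as deviations from the mean of their tissue and ZT showed no pairing by these codes: the median correlation of libraries from the same animal lay between -0.0572 and 0.0420, and an animal's own library was the best match in 0 to 2 cases per pair of tissues. With the animal as a block the tissue calls numbered 59, 111, 55, 334, 339 and 340 for cortex with striatum, cortex with hypothalamus, striatum with hypothalamus, and cortex, striatum and hypothalamus with liver. No pair of libraries held duplicate counts; the smallest chi-square per degree of freedom over the 1214 pairs of libraries of the same group was 11.6.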

Results

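Right cortex (78 libraries), right striatum (46), hypothalamus (72) and liver (77) were profiled by small RNA sequencing in a series that ran from 0 to 36 h, with 13 time points, or 12 in striatum, which had none at ZT15. Times 24 h apart were joined, which gave 8 ZT groups per tissue. In cortex ZT0 to ZT12 had 12 libraries each and the later times 6. Hypothalamus had 12, 11, 12, 10, 12, 5, 5 and 5 libraries from ZT0 to ZT21, liver had 12, 12, 12, 11, 12, 6, 6 and 6, and striatum had 7, 6, 8, 9 and 9 from ZT0 to ZT12, 2 at ZT18 and 5 at ZT21. The median library held 3119447.5 counts in cortex, 2024602 in striatum, 2120502 in hypothalamus and 2920409 in liver.

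A few miRNAs held a large share of the counts. The first of them differed between brain and liver, while miR-22 and miR-30a were among the 5 most abundant in every tissue. miR-127 (chromosome 12, 109592846 to 109592915 in GRCm38) and miR-434 (chromosome 12, 109594506 to 109594599), both from the imprinted Dlk1-Dio3 cluster, whose miRNAs are transcribed from the maternal chromosome, led in brain. miR-127 held 17.4% ± 2.04 (SD, n = 78) of the counts in cortex, 17.7% ± 3.55 (n = 46) in striatum and 25.7% ± 2.07 (n = 72) in hypothalamus. miR-434 held 7.77% ± 1.22, 11.4% ± 3.11 and 11.1% ± 1.62. In liver (n = 77) miR-192 (chromosome 19, 6264844 to 6264932), a miRNA abundant in hepatocytes, held 29.1% ± 2.30 and miR-22 (chromosome 11, 75463716 to 75463810, in exons of Mir22hg and Tlcd2) held 16.9% ± 1.90. They were followed by miR-148a (chromosome 6, 51269812 to 51269910) with 9.63% ± 0.779, miR-30a (chromosome 1, 23272269 to 23272339) with 7.36% ± 0.682 and miR-10a, which lies in the Hoxb cluster (chromosome 11, 96317165 to 96317274), with 4.995% ± 1.01. The cortex also gave 8.44% ± 0.900 to miR-22, 7.97% ± 0.827 to miR-30a and 3.94% ± 0.378 to miR-27b (chromosome 13, 63300712 to 63300784). The other leaders were miR-30a (6.61% ± 1.53), miR-22 (5.34% ± 1.40) and miR-125a (4.66% ± 0.972; chromosome 17, 17830812 to 17830879, in an exon of Spaca6) in striatum, and miR-125a (4.39% ± 0.63), miR-30a (4.16% ± 0.485) and miR-22 (3.45% ± 0.325) in hypothalamus. The 5 most abundant miRNAs of each tissue together took 45.5% ± 1.0 of the counts in cortex, 45.8% ± 2.21 in striatum, 48.8% ± 1.38 in hypothalamus and 68.1% ± 1.12 in liver. These shares rank the deposited counts. Counts of miRNAs with several genomic copies depend on a read handling that is not stated, and some were low. In liver miR-26a-1 and miR-26a-2 averaged 3.31 and 8.50 CPM.

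The time series asked which miRNAs follow a 24 h rhythm in each tissue. miR-5099 (chromosome 12, 36816205 to 36816278, outside annotated genes) varied over the day in cortex, hypothalamus and liver. Its peak-to-trough log2 ratio was 0.57 ± 0.08 (SE, n = 78) in cortex with the peak at ZT8.38 (± 0.503 h; adjusted p = 8.067e-07). It was 0.68 ± 0.10 (n = 72) in hypothalamus at ZT8.18 (± 0.506 h; adjusted p = 2.268e-06). In liver it was 0.60 ± 0.08 (n = 77) at ZT6.33 (± 0.456 h; adjusted p = 6.2e-08). In CPM it went from 64.1 ± 11.4 at ZT21 to 93.6 ± 7.04 at ZT12 in cortex, from 61.5 ± 13.6 at ZT0 to 100.6 ± 20.3 at ZT6 in hypothalamus and from 234.7 ± 41.6 at ZT18 to 360.8 ± 44.9 at ZT6 in liver. In striatum (n = 46) its ratio was 0.49 ± 0.18 with adjusted p = 0.998, and 0.75 with adjusted p = 0.00657 once the 8 libraries that stood apart were left out. In striatum that fit lacked ZT21 replicate 3 and also ZT9 replicate 6, which held 26341 counts. No other alternative in which miR-5099 was followed passed, and over these the adjusted p ran from 0.00657 to 0.999. It was not followed in striatum with each library left out in turn. A permutation test of its striatum curve alone, described below, gave p = 0.00110. With library run as a term miR-5099 stayed called in cortex (adjusted p = 5.128e-07), hypothalamus (7.062e-08) and liver (4.788e-09). Some alternatives, given below, called more miRNAs in cortex and hypothalamus, but the main fit called miR-5099 alone, of 393 and 380 tested. There 16 and 5 had an unadjusted p under 0.05 against 19.7 and 19 expected by chance. The call was shared by cortex and hypothalamus (adjusted p = 0.0163 by Fisher's exact test over 368 miRNAs, 0.00272 expected). It was also shared by cortex and liver and by hypothalamus and liver (adjusted p = 0.110 for both, 0.0543 and 0.0550 expected). Many animals were common to the tissues.

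**Figure D1:**
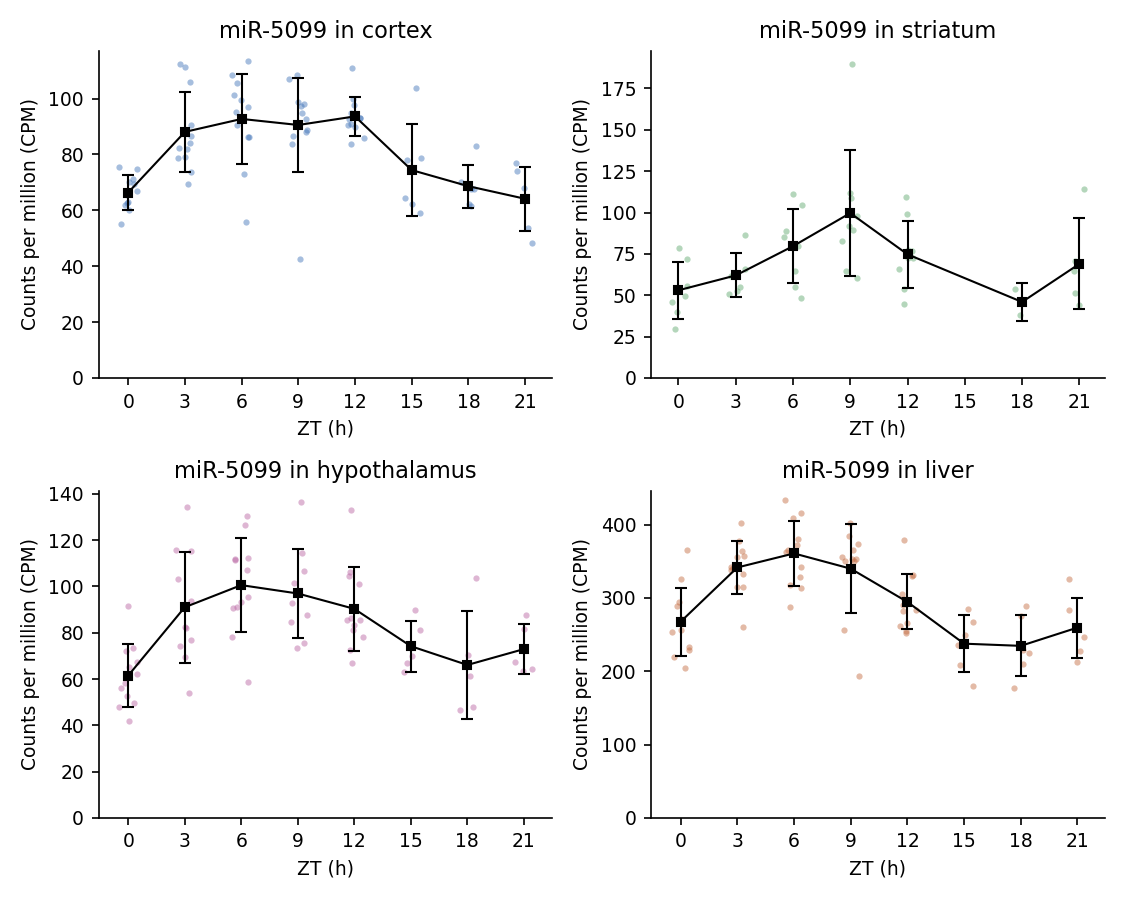
miR-5099 in CPM (vertical axes, from 0) against ZT in hours (horizontal axes) for the 4 tissues; coloured points are libraries, spread sideways for view, and black squares with bars are the mean and SD of each ZT. In liver the mean went from 234.7 at ZT18 to 360.8 at ZT6.

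In liver 12 of 241 tested miRNAs were rhythmic, and miRNAs of white blood cells were among them. miR-150 (chromosome 7, 45121757 to 45121821), a miRNA of mature lymphocytes, had a peak-to-trough log2 ratio of 1.34 ± 0.16 (SE, n = 77), which is 2.53-fold, with its peak at ZT4.96 (± 0.409 h; adjusted p = 1.31e-09). It went from 58.7 ± 15.9 CPM (SD, n = 6) at ZT15 to 194.6 ± 70.0 (n = 12) at ZT6. miR-223 (X chromosome, 96242817 to 96242926), known from granulocytes and monocytes, had 0.65 ± 0.10 (peak ZT4.58, adjusted p = 3.156e-06). miR-142a (chromosome 11, 87756864 to 87756927), found in all blood cell lineages, had 0.56 ± 0.09 (peak ZT4.72, adjusted p = 2.108e-06). miR-342 (chromosome 12, 108658620 to 108658718, an intron of Evl), abundant in lymphocytes, had 0.49 ± 0.10 (peak ZT5.98, adjusted p = 0.00103). Its mean was 64.7 CPM in liver and 1479 in cortex. In the preset immune list 3 of 5 miRNAs were called, and 4 of 5 when adjusted over the list alone. The list held a larger share of calls than the other miRNAs (adjusted p = 0.0162 by Fisher's exact test). Its other members were miR-146a with 0.35 ± 0.14 (peak ZT13.7, adjusted p = 0.219) and miR-155 with 0.32 ± 0.18 (adjusted p = 0.492). With library run as a term the adjusted p was 2.066e-10 for miR-150, 4.987e-06 for miR-223, 2.635e-06 for miR-142a and 0.00912 for miR-342. In the preset erythroid list no miRNA was called in liver; miR-451a, the abundant miRNA of red blood cells, had 0.53 ± 0.19 with its peak at ZT8.85 and adjusted p = 0.146.

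**Figure D2:**
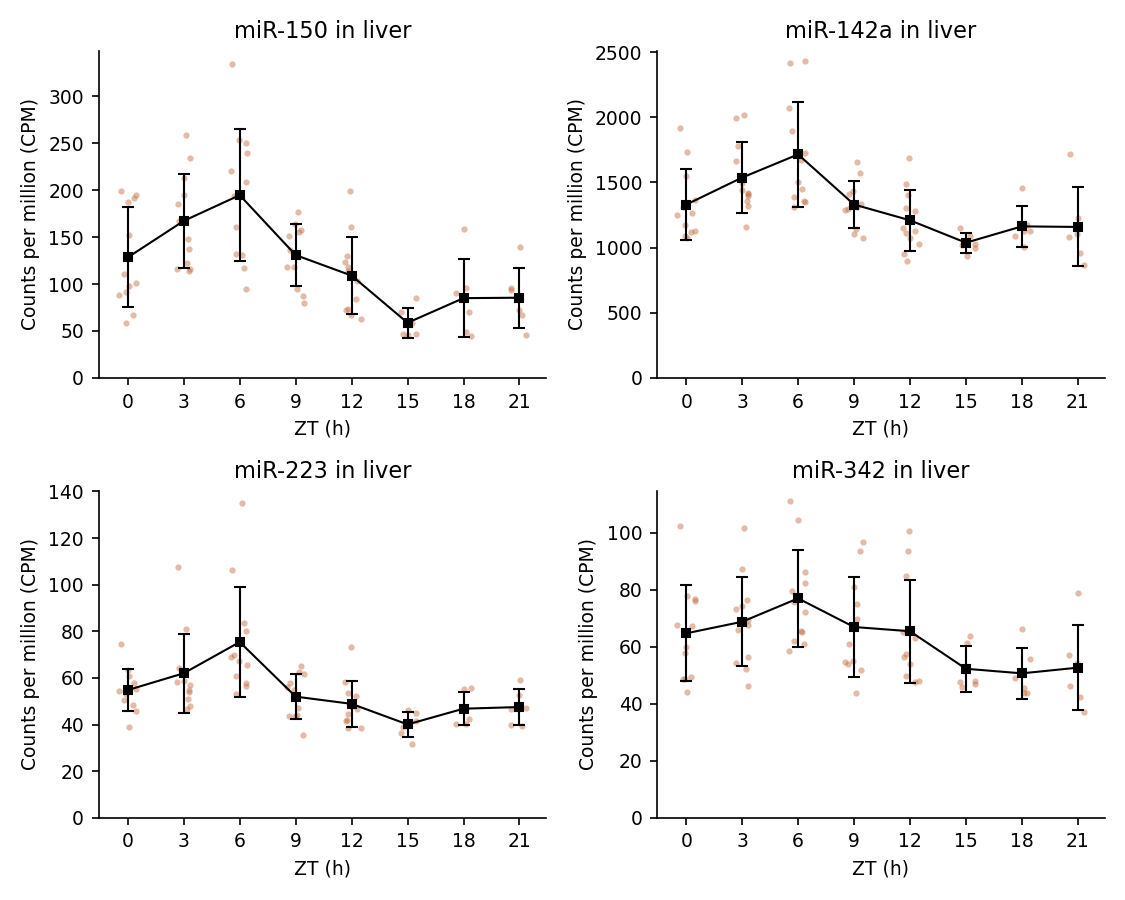
miR-150, miR-142a, miR-223 and miR-342 in liver in CPM (vertical axes, from 0) against ZT in hours (horizontal axes); coloured points are the 77 libraries, spread sideways for view, and black squares with bars are the mean and SD of each ZT. miR-150 had its highest mean at ZT6 (194.6) and its lowest at ZT15 (58.7).

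Outside the blood cell miRNAs, miR-29b-1 (chromosome 6, 31063023 to 31063093), of a family that represses collagens, had the largest ratio in liver, 1.66 ± 0.19 or 3.16-fold, with its peak at ZT7.61 (± 0.379 h; adjusted p = 1.461e-10). Its level was low, 7.44 ± 2.63 CPM (SD, n = 11) at ZT9 and 2.05 ± 1.32 (n = 6) at ZT21. The other copy of the same mature miRNA, miR-29b-2, had 0.05 ± 0.18 at a mean of 3.06 CPM (adjusted p = 0.977), miR-29a had 0.03 ± 0.04 (adjusted p = 0.860) and miR-29c 0.08 ± 0.05 (adjusted p = 0.580). How reads shared by such copies were counted is not stated. miR-16-1 (chromosome 14, 61631880 to 61631972, an exon of Dleu2), of a family that represses cell cycle genes, had 0.38 ± 0.07 (peak ZT6.55, adjusted p = 5.563e-04). Of the remaining calls, miR-26a-2 (chromosome 10, 126995530 to 126995613, in Ctdsp2) had 0.55 ± 0.14 (adjusted p = 0.0237) and miR-331 (chromosome 10, 93963768 to 93963863, in Vezt) 0.45 ± 0.12 (adjusted p = 0.0437). miR-874 (chromosome 13, 58023125 to 58023200, an intron of Klhl3) had 0.28 ± 0.07 (adjusted p = 0.0237) and miR-185 (chromosome 16, 18327401 to 18327465, an intron of Tango2) 0.26 ± 0.07 (adjusted p = 0.0439). miR-23b (chromosome 13, 63300484 to 63300557) had 0.19 ± 0.05 (adjusted p = 0.0237). Of the 12 peaks, 5 fell in ZT0 to ZT6, 6 in ZT6 to ZT12 and 1 in ZT12 to ZT18. The last 5 calls ended with no filter on low counts (adjusted p = 0.0862, 0.121, 0.0862, 0.0862 and 0.0699) and with 0 to 21 h or 15 to 36 h alone. The call of miR-331 also ended with library run as a term (adjusted p = 0.129). Over the alternatives their adjusted p reached 0.333 for miR-26a-2, 0.189 for miR-331, 0.268 for miR-874, 0.333 for miR-185 and 0.463 for miR-23b. With 1 library left out the largest adjusted p was 0.0929 for miR-26a-2 (without ZT18 replicate 5), 0.114 for miR-331 (ZT15 replicate 4), 0.0674 for miR-874 (ZT0 replicate 3), 0.131 for miR-185 (ZT12 replicate 7) and 0.0835 for miR-23b (ZT12 replicate 4). The lowest values over the alternatives were 3.878e-04, 1.507e-05, 0.00655, 0.00948 and 0.0160.

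Among miRNAs linked to the clock in the literature, 4 of 32 tested in liver were called (miR-142a, miR-16-1, miR-185 and miR-29b-1; 4 adjusted over the list alone), with an odds ratio of 3.56 against the other miRNAs that missed the threshold by Fisher's exact test once adjusted over the lists (p = 0.0589, adjusted p = 0.530). miR-122 (chromosome 18, 65248861 to 65248926), the main miRNA of hepatocytes, had a ratio of 0.04 ± 0.03 (n = 77, adjusted p = 0.635). miR-192 had 0.11 ± 0.06 (adjusted p = 0.487), miR-378a 0.11 ± 0.04 (0.199), miR-181d 0.21 ± 0.08 (0.208), miR-24-1 0.67 ± 0.22 (0.138) and miR-34a 0.30 ± 0.13 (0.321). In brain edgeR called 0 clock-linked miRNAs of 33 in cortex, of 32 in striatum and of 33 in hypothalamus. miR-132, a miRNA induced by neuronal activity and by light in the suprachiasmatic nucleus, had 0.12 ± 0.10 in cortex (adjusted p = 0.986) and 0.06 ± 0.08 in hypothalamus (adjusted p = 0.999). miR-219a-2, known from oligodendrocytes, had 0.18 ± 0.08 in cortex (adjusted p = 0.986). Adjusted over the list alone, 3 clock-linked miRNAs were called in cortex, all of the miR-183 cluster. These were miR-96 with 2.18 ± 0.57, miR-183 with 1.93 ± 0.51 and miR-182 with 1.86 ± 0.51, with peaks near ZT17.7 and adjusted p of 0.0829, 0.119 and 0.123 over all miRNAs. In cortex ZT15 replicate 1 miR-182 stood at 23573 CPM against a cortex median of 1020 and miR-183 at 2227 against 85.1.

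Other lists were called in part when adjusted over the list alone. In cortex these were 5 of 5 miR-200 family members, 3 of 3 of the miR-183 cluster and 1 of 6 choroid plexus miRNAs; the miR-200 family member miR-429 stood at 1540 CPM in cortex ZT15 replicate 1 against a median of 43.8. In striatum they were 2 erythroid miRNAs, miR-486a (1.05 ± 0.34, peak ZT21.4) and miR-486b (0.99 ± 0.38), and the liver-enriched miR-194-2 (0.95 ± 0.32, peak ZT19.1). The rhythm of miR-194-2 also differed between striatum and liver (adjusted p = 0.0260 by edgeR), but that call ended without striatum ZT21 replicate 3. In hypothalamus 1 neuronal miRNA was called, miR-124-2 (0.51 ± 0.13, peak ZT11.0, adjusted p = 0.153 over all miRNAs and 0.0145 over the list). In liver they were 3 of 10 Dlk1-Dio3, 1 muscle or mural and 1 miR-29 miRNA. Of all lists in the 4 tissues the liver immune list alone passed Fisher's exact test after adjustment over the lists.

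In striatum 2 miRNAs were called, miR-497a (chromosome 11, 70234717 to 70234800) and its neighbour miR-195a (chromosome 11, 70235042 to 70235135), which share a seed with miR-16. Their ratios were 2.48 ± 0.54 (SE, n = 46; peak ZT19.4, adjusted p = 0.00188) and 2.28 ± 0.54 (peak ZT19.0, adjusted p = 0.00456). Striatum ZT21 replicate 3 held 4241 CPM of miR-497a and 3257 of miR-195a, against striatum medians of 176 and 135. Without it the ratios were 0.16 and 0.12, with adjusted p = 0.996 for both. With library run as a term they were 0.93 and 0.91, with adjusted p = 0.905 for both. Over all alternatives the adjusted p ran from 5.646e-04 to 0.999 and from 0.00232 to 0.999. An unadjusted p under 0.05 was seen for 11 miRNAs against 19 expected by chance in striatum and for 49 against 12.1 in liver.

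The rhythms were then compared between tissues. miR-150 and miR-142a were rhythmic in liver to an extent that differed from cortex (adjusted p = 0.00426 and 0.0273), and miR-150 also differed between liver and hypothalamus (adjusted p = 0.00157). miR-29b-1, with a mean of 4.86 CPM in liver, differed between liver and cortex (adjusted p = 1.406e-07), striatum (1.24e-04) and hypothalamus (0.00157). miR-122, with 2.82 CPM in hypothalamus, was called between liver and hypothalamus (adjusted p = 0.00343), but without hypothalamus ZT0 replicate 12, which held 58.4 CPM, the adjusted p was 0.626. miR-376b (0.00913) and miR-379 (0.0360) of the Dlk1-Dio3 cluster, with 1.90 and 3.77 CPM in liver, were called between cortex and liver. With 1 library left out the largest adjusted p was 0.0446 for miR-376b (liver ZT15 replicate 1) and 0.111 for miR-379 (liver ZT15 replicate 4), whose call ended in 14 such fits. That of miR-142a against cortex ended in 4, with 0.0705 as the largest (cortex ZT15 replicate 3). miR-497a and miR-195a differed between striatum and cortex (adjusted p = 5.753e-05 for both), hypothalamus (9.449e-05 and 3.728e-04) and liver (1.376e-05 and 2.061e-05). Calls numbered 2 of 385 for cortex with striatum, 0 for cortex with hypothalamus and 3 of 370 for striatum with hypothalamus. With liver they numbered 5 of 372 for cortex, 7 for striatum and 3 of 373 for hypothalamus. For cortex with hypothalamus 13 miRNAs had an unadjusted p under 0.05 by edgeR against 18.8 expected, and DESeq2 also called 0. The animal as a block was fitted in limma voom in place of edgeR. That fit called 0, 0 and 1 for the striatum pairs with cortex, hypothalamus and liver. It called 4 and 3 for liver with cortex and with hypothalamus. Tool and block changed together there, so the part of each was not tested. Without striatum ZT21 replicate 3 alone the striatum pairs gave 0, 0 and 1, as they did without the 8 libraries that stood apart.

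The largest differences between tissues set liver against brain. miR-122 averaged 21398 ± 1647 CPM in liver (SD, n = 77) and 2.82 ± 6.74 in the brain region nearest to it, a log2 ratio of 14.91 ± 0.11 (SE; adjusted p = 3.562e-219 by edgeR). miR-192 followed with 291461 ± 22974 against 2386 ± 822 CPM (8.86 ± 0.05), and miR-194-2, which is transcribed with it (chromosome 19, 6264643 to 6264728), with 941.4 ± 151 against 20.9 ± 14.5 (7.37 ± 0.07). miR-1948 (chromosome 18, 12714811 to 12714895, an intron of Ttc39c; 8.58 ± 0.09), miR-10a (8.19 ± 0.07) and miR-802 (chromosome 16, 93369720 to 93369816; 7.57 ± 0.09), a miRNA of liver metabolism, completed the 6 with the largest smallest ratio. On the brain side miR-434 was higher in cortex by 8.77 ± 0.05, miR-127 by 7.13 ± 0.04 and miR-136, also of the Dlk1-Dio3 cluster, by 6.97 ± 0.06. Of 414 miRNAs 334 were called between cortex and liver (221 higher in cortex, 113 higher in liver), 339 between striatum and liver (220 and 119) and between hypothalamus and liver 217 were higher in hypothalamus and 121 in liver. Scaling moved these ratios. The median over all miRNAs for cortex against liver was 1.29 with TMM, 1.45 with DESeq2 size factors and 3.07 with library totals. The corresponding medians were 1.39, 1.70 and 3.31 for striatum and 1.27, 1.71 and 3.21 for hypothalamus. With library totals the calls split 300 and 49, 292 and 55, and 293 and 51. They split 349 and 247, 352 and 254, and 351 and 265 with no filter on low counts. Liver and brain libraries shared 1 run, which held 25 liver libraries and hypothalamus ZT0 replicate 12. Across miRNAs, that library correlated at 0.992 with the hypothalamus median and at 0.439 with the liver median. A fit with library run as a term was added after the results were seen, and for liver against brain it rests on that library. In it the hypothalamus to liver log2 ratio was -10.30 ± 0.30 for miR-122, of which that library held 58.4 CPM, -8.40 ± 0.20 for miR-192 and 9.30 ± 0.29 for miR-434. Of the calls against liver it kept 307 for cortex, 318 for striatum and 315 for hypothalamus, while 3 for cortex and 1 for striatum changed sign.

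Some of the preset lists separated liver from brain, while others were not called. Of 9 liver-enriched miRNAs 8 were higher in liver than in cortex and 1 was lower (median log2 ratio -7.52, adjusted p = 6.724e-05 by camera), with miR-148a at -6.57 ± 0.05 and miR-101b at -3.90 ± 0.03. All 18 neuronal miRNAs were higher in cortex (adjusted p = 7.817e-05), as were all 48 tested members of the Dlk1-Dio3 cluster (adjusted p = 4.555e-11). These lists were also called for striatum (8.549e-05, 1.532e-04 and 3.381e-11) and hypothalamus (1.061e-04, 2.64e-04 and 5.944e-11) against liver. With TMM all 4 erythroid miRNAs were higher in liver than in cortex (adjusted p = 0.0424 by camera, but adjusted p = 0.212 with an estimated correlation). There miR-144 had -3.35 ± 0.08, miR-451a -2.58 ± 0.09 and miR-486a -2.26 ± 0.08. The size of these ratios and of the miR-17/92 ratios below depends on scaling. In CPM, which use library totals, miR-486a averaged 22.2 in cortex and 28.4 in liver. For the erythroid list in striatum against liver the adjusted p was 0.0409, and adjusted p = 0.215 with an estimated correlation. Of 11 members of the miR-17/92 families 9 were higher in liver and 1 in cortex (adjusted p = 7.526e-04, but adjusted p = 0.0616 with an estimated correlation). miR-92a-1 had -4.10 ± 0.04, miR-25 -2.36 ± 0.03 and miR-93 -2.03 ± 0.04, while miR-92b, a miRNA of neural progenitors, had 6.87 ± 0.04. That list was also called for striatum (0.00103, and adjusted p = 0.0778 with an estimated correlation) and hypothalamus (5.956e-04, and adjusted p = 0.0613 with an estimated correlation). Clock-linked miRNAs split 8 and 19 of 35 between cortex and liver (adjusted p = 0.00322, but adjusted p = 0.0605 with an estimated correlation), and they were called with both correlations for striatum (2.935e-04 and 0.0134) and hypothalamus (2.64e-04 and 0.0125) against liver. Of all 27 list calls in the 6 pairs of tissues 11 held with an estimated correlation: liver-enriched, neuronal and Dlk1-Dio3 miRNAs in the 3 pairs with liver, and the clock-linked miRNAs in both pairs just named. Adjusted over the list alone, each list gave the same count of called miRNAs in every pair.

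Blood and vessel miRNAs differed by member. In the immune list miR-223 (-4.05 ± 0.07), miR-142a (-3.30 ± 0.06), miR-146a (-3.03 ± 0.10) and miR-155 (-2.66 ± 0.08) were higher in liver than in cortex. miR-150 was higher in cortex (2.78 ± 0.09), with 3256 ± 1147 CPM there and 129.9 ± 61.1 in liver. The list was not called (adjusted p = 0.0625). The endothelial miR-126a had -3.06 ± 0.04. The muscle and mural list had 2 miRNAs higher in liver, miR-143 (-2.36 ± 0.05) and miR-145a (-1.42 ± 0.05), adjusted p = 0.0919. With library totals miR-143 fell below the ratio minimum at -0.44 and miR-145a reversed to 0.50. The Hox list had miR-10a (-9.44 ± 0.07) and miR-10b (-3.74 ± 0.13) higher in liver (adjusted p = 0.0620). The 5 tested miR-200 family members, known from epithelia, were higher in liver (adjusted p = 0.0919), with miR-200b at -3.19 ± 0.20 and miR-141 at -1.89 ± 0.27. The 3 members of the miR-183 cluster, known from sensory cells, were also higher in liver (adjusted p = 0.193), with miR-182 at -2.59 ± 0.17. With library totals miR-141, miR-429, miR-183 and miR-96 reversed to 0.0593, 0.59, 0.39 and 0.46. With library run as a term these 4 and miR-182 missed the threshold (adjusted p = 0.159, 0.0945, 0.168, 0.125 and 0.0564), at ratios of -3.13, -3.07, -1.93, -3.38 and -2.89. In the let-7 family, which marks differentiated cells, 2 of 13 were higher in cortex and 6 in liver (adjusted p = 0.0620). let-7e had 2.11 ± 0.04 and let-7g -0.68 ± 0.03, which library totals reversed to 1.23. The let-7 list was called for striatum (0.0407, but adjusted p = 0.355 with an estimated correlation) and hypothalamus (0.0136, but adjusted p = 0.242 with an estimated correlation) against liver. In the miR-30 family 1 of 7 was higher in cortex and 3 in liver. miR-384, counted with that family and known from brain, had 925 ± 159 CPM in cortex and 0.0723 in liver. miR-30a had -1.80 ± 0.04, which library totals reversed to 0.11. The median of the miR-30 list was -0.88 and its mean 0.75. For hypothalamus against liver, where its median was -1.26 and its mean 0.29, the list was called (0.0491, but adjusted p = 0.242 with an estimated correlation). Of 4 miR-29 miRNAs 1 was higher in cortex, miR-29b-2 (1.71 ± 0.07, or 0.94 with library run as a term), and of 3 Sfmbt2 cluster miRNAs 2, with miR-669c at 2.22 ± 0.16. The 5 tested miR-34 and miR-449 miRNAs were higher in cortex (adjusted p = 0.313), with miR-34c at 4.58 ± 0.12. All 4 neuroendocrine (adjusted p = 0.250; miR-375 had -6.982e-04 with library run as a term) and all 6 choroid plexus miRNAs (adjusted p = 0.202) were higher in cortex than in liver. Of 3 oligodendrocyte miRNAs 2 were higher in cortex (adjusted p = 0.602), miR-338 by 4.38 ± 0.04, and miR-219a-1 was lower (-2.19 ± 0.06, or -0.26 with library totals).

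Within the brain, hypothalamus had the most enriched miRNAs and striatum the fewest. Hypothalamus had 20 miRNAs higher than in the 3 other tissues, 12 of them with mean CPM of at least 100. miR-653 (chromosome 6, 3721301 to 3721385, an intron of the calcitonin receptor gene Calcr) stood at 395.0 ± 74.4 CPM (SD, n = 72) against 85.5 ± 60.6 in striatum (n = 46), a log2 ratio of 2.28 ± 0.12. miR-7b (chromosome 17, 56242988 to 56243098), a miRNA of hypothalamic neurons, had 396.3 ± 102 against 105 ± 52.5 (1.93 ± 0.08), and miR-7a-2 138.03 ± 25.5 against 58.3 ± 25.3 (1.28 ± 0.09). miR-3547 (chromosome 17, 25245551 to 25245638, an intron of Baiap3) had 1.92 ± 0.14 and miR-217 (chromosome 11, 28763728 to 28763835) 1.73 ± 0.13. miR-375 (chromosome 1, 74900658 to 74900721), a miRNA of endocrine cells in the pituitary and pancreas, had the largest ratio, 2.84 ± 0.26, with a mean of 3488 ± 15966 CPM. Without the 8 libraries that stood apart its striatum to hypothalamus log2 ratio was -1.31, against -2.84 with all, and with the animal as a block it was -1.67. Hypothalamus ZT0 replicate 9 and ZT9 replicate 8 held 111518 and 80244 CPM of miR-375 against a median of 645 in the other hypothalamus libraries, and 7807 and 5938 CPM of miR-141, whose median was 67.3.

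**Figure D3:**
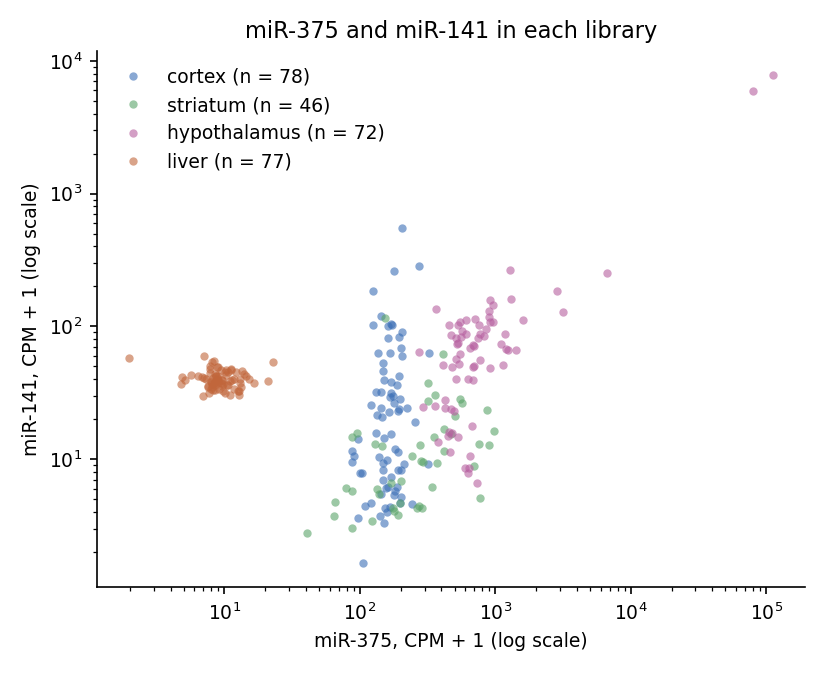
miR-375 (horizontal axis) against miR-141 (vertical axis) in CPM plus 1 on log axes, with 1 point per library and 1 colour per tissue. The hypothalamus libraries ZT0 replicate 9 (111518 and 7807 CPM) and ZT9 replicate 8 (80244 and 5938 CPM) sit apart from the other libraries.

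Cortex had 6 miRNAs higher than in the 3 other tissues, 4 of them with mean CPM of at least 100. miR-128-1 (chromosome 1, 128202361 to 128202430, an intron of R3hdm1) stood at 14730 ± 3137 CPM (SD, n = 78) against 5421 ± 2039 in striatum (log2 ratio 1.43 ± 0.06). miR-128-2 (chromosome 9, 112118636 to 112118711, an intron of Arpp21) stood at 7235 ± 1082 against 3360 ± 795 (1.10 ± 0.06). Both give the same mature neuronal miRNA. miR-34a (chromosome 4, 150068454 to 150068555), a p53 target, had 1.32 ± 0.10 and miR-132 (chromosome 11, 75173682 to 75173747) 1.07 ± 0.07. With DESeq2 size factors miR-128-2 and miR-132 fell below the ratio minimum, at 0.96 and 0.93. In cortex ZT9 replicate 9 miR-128-1 was 7316 CPM against a cortex median of 14227. Striatum had 3 such miRNAs, 1 of them with mean CPM of at least 100: miR-1298 (X chromosome, 147064905 to 147065002, in an intron of the serotonin receptor gene Htr2c), with 2801 ± 2918 CPM (n = 46) against 868 ± 112 in hypothalamus (1.69 ± 0.14, or 1.09 with the animal as a block). It belongs to the preset choroid plexus list, of which 5 of 6 miRNAs were higher in striatum than in cortex and 2 of 6 higher than in hypothalamus. The SD of miR-1298 in striatum exceeded its mean. Whether choroid plexus in some samples gave this level was not tested, so it is not shown to come from striatal cells.

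Between cortex and striatum 58 miRNAs were called (26 higher in cortex, 32 in striatum), between cortex and hypothalamus 113 (44 and 69) and between striatum and hypothalamus 56 (21 and 35). Scaling shifted these splits. With DESeq2 size factors they were 19 and 49, 29 and 96, and 15 and 39. The median ratio over all miRNAs was then -0.18, -0.31 and -0.13, against -0.04, -0.04 and 0.00 with TMM. Choroid plexus miRNAs were lower in cortex than in striatum in 5 of 6 cases (adjusted p = 0.00161 by camera, but adjusted p = 0.315 with an estimated correlation). miR-448, also within Htr2c, had -2.51 ± 0.14, miR-1298 -2.20 ± 0.14 and miR-204 (chromosome 19, 22750605 to 22750672, an intron of Trpm3), the abundant miRNA of choroid plexus epithelium, -2.07 ± 0.12. miR-204 stood at 5683 ± 4427 CPM in cortex, 23622 ± 21045 in striatum and 17592 ± 1723 in hypothalamus, and its level in cortex ZT0 replicate 1 was 41841. Neuronal miRNAs were higher in cortex than in striatum for 3 of 18 (adjusted p = 0.00161, but adjusted p = 0.0597 with an estimated correlation). They were higher in cortex than in hypothalamus for 8 of 18, with 2 lower (adjusted p = 0.0166, but adjusted p = 0.185 with an estimated correlation). Clock-linked miRNAs were higher in cortex than in striatum for 8 of 35 (adjusted p = 0.00161, but adjusted p = 0.0597 with an estimated correlation), and they were higher in cortex than in hypothalamus for 7 of 35 (adjusted p = 0.0101, but adjusted p = 0.184 with an estimated correlation). Of 48 Dlk1-Dio3 miRNAs 7 were higher in hypothalamus than in cortex (adjusted p = 0.0467, but adjusted p = 0.528 with an estimated correlation). In the let-7 family 1 of 13, let-7b, was higher in cortex (1.02 ± 0.05; adjusted p = 0.0448, but adjusted p = 0.528 with an estimated correlation). The 3 Sfmbt2 cluster miRNAs were higher in hypothalamus than in cortex (adjusted p = 0.166), with miR-669c at -1.50 ± 0.08.

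The miR-200 family and the miR-183 cluster were lower in striatum than in either other brain region. All 5 tested miR-200 miRNAs were higher in cortex than in striatum (adjusted p = 0.145 by camera) and lower in striatum than in hypothalamus (adjusted p = 0.0933), with miR-141 at 1.89 ± 0.35 and -4.20 ± 0.35 and miR-200b at 2.32 ± 0.26 for the first. All 3 miR-183 cluster miRNAs did the same (adjusted p = 0.145 and 0.219), with miR-182 at 2.26 ± 0.20 and -1.85 ± 0.21. Without the 8 libraries that stood apart miR-141 had 1.59 and -2.68 and miR-182 2.25 and -1.75, and all 5 miR-200 and all 3 miR-183 cluster miRNAs stayed past both thresholds. Among the libraries left out, cortex ZT15 replicate 1 held 552 CPM of miR-141 against a cortex median of 14.6, and the hypothalamus libraries with high miR-375 held the highest miR-141. Neuroendocrine miRNAs were lower in striatum than in hypothalamus for 3 of 4 (adjusted p = 0.0668) and in cortex for 3 of 4 (adjusted p = 0.101). No list was called by camera between striatum and hypothalamus. The oligodendrocyte miR-338 stood at 4403 ± 674 CPM in cortex, 7521 ± 1823 in striatum and 3995 ± 719 in hypothalamus, a cortex to striatum ratio of -0.76 ± 0.05 that missed the ratio minimum.

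Times 24 h apart were compared to ask whether the second passage through ZT0 to ZT12 repeated the first. In cortex (30 libraries in each passage) 70 miRNAs were higher and 54 lower in the second, with a median absolute log2 ratio of 0.24. miR-182 went from 1052 ± 1091 to 2256 ± 2593 CPM (SD; log2 ratio 1.09 ± 0.29, adjusted p = 0.00497) and miR-183 from 105 ± 130 to 199 ± 231 (0.94 ± 0.30, adjusted p = 0.0152). miR-187 went from 232.2 ± 184.6 to 418.8 ± 141.8 (0.92 ± 0.22, adjusted p = 0.00215). miR-6240 (chromosome 5, 114851948 to 114852064) went from 662 ± 462 to 305 ± 294 (-1.19 ± 0.29, adjusted p = 0.00215) and miR-6236 (chromosome 9, 110281287 to 110281409) from 2780 ± 1532 to 1448 ± 862 (-0.97 ± 0.21, adjusted p = 6.703e-04). All 3 miR-183 cluster miRNAs were higher in the second passage (p = 0.0350 by Fisher's exact test, adjusted p = 0.350 over the lists). Of 18 neuronal miRNAs 5 were higher and 6 lower, of 47 Dlk1-Dio3 miRNAs 11 were higher and 2 lower, and of 13 let-7 miRNAs 5 were lower. The neuronal list had p = 0.0176 by Fisher's exact test and adjusted p = 0.350, and no list passed after adjustment. Mean totals in cortex were 2719873 ± 873011 in the first passage and 3477480 ± 794805 in the second. With library run as a term 91 were called, 81 of them among those miRNAs. With the log2 library total as a term 28 were called, all among those miRNAs, whose median absolute ratio was 0.15 in place of 0.24 with a median SE of 0.07 in both fits. In that fit miR-6240 (-0.42), miR-6236 (-0.35) and miR-183 (0.96) missed the threshold, with adjusted p = 0.157, 0.0944 and 0.0678. Over all alternatives the lowest adjusted p was 2.49e-04, 6.246e-05 and 0.00751. By edgeR 0 miRNAs differed in striatum (47 with an unadjusted p under 0.05), 0 of 361 in hypothalamus (4) and 0 of 232 in liver (11); DESeq2 called 0, 0 and 1. The passage difference in cortex itself differed from striatum for 46 miRNAs, from hypothalamus for 57 and from liver for 24.

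**Figure D4:**
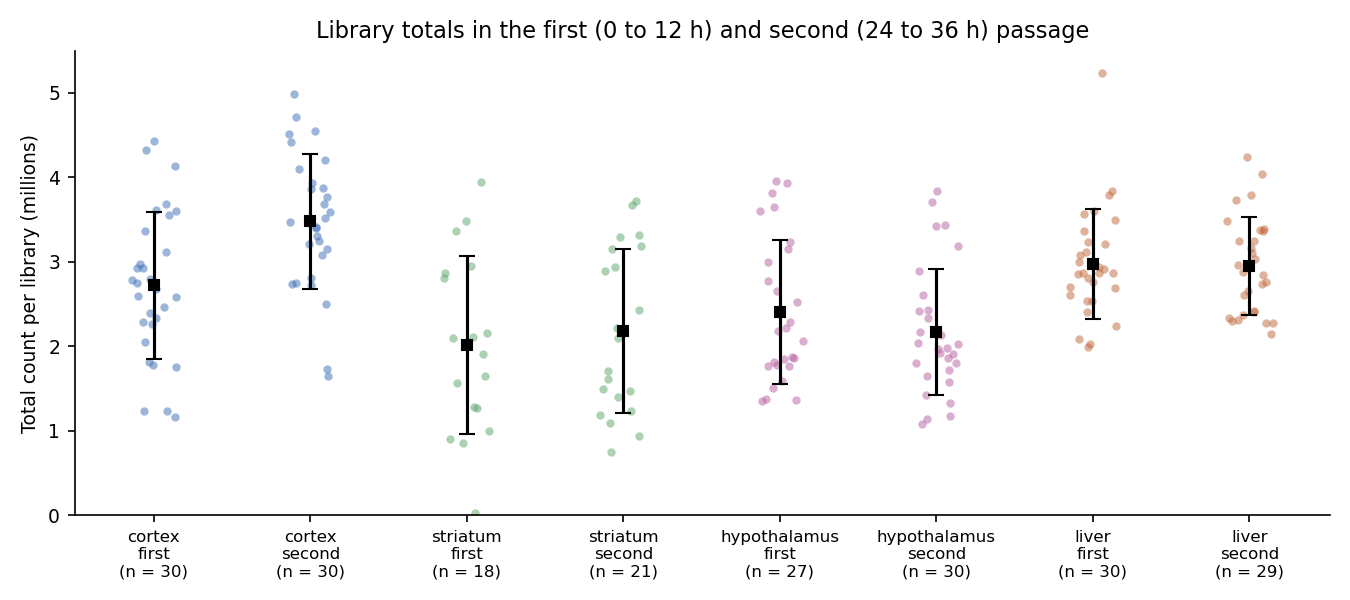
Total counts per library (vertical axis, from 0) in the first passage (0 to 12 h) and the second (24 to 36 h) in each tissue; points are libraries and black squares with bars are the mean and SD. The cortex means were 2719873 and 3477480, each over 30 libraries.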

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

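The tests of explanations and the comparisons with other splits of the libraries were chosen after the results were seen. The comparison of libraries with their group, made in the smaller groups, and the tests of rhythm between tissues were planned.

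In liver miR-150, miR-223, miR-142a and miR-342, known from white blood cells, peaked together. Their mean followed a 24 h curve with a peak-to-trough log2 ratio of 0.73 at ZT5.07 (permutation p = 1e-05, the smallest the permutations can give, n = 77). The 4 were chosen after they were seen to do so, so that p adds no support. The 5 measured miRNAs of the preset immune list had 0.49 at ZT5.16 (permutation p = 2e-05). miR-150 and miR-342 stood higher in cortex, at 3256 and 1479 CPM against 129.9 and 64.7 in liver, so they need not come from leukocytes alone. Library run as the whole cause was argued against, since all 4 passed with run as a term (largest adjusted p = 0.00912). A common change in the share of leukocytes cannot be told apart from changes of separate types: miR-150, picked for its larger ratio, followed a further curve of 0.83 beyond the other 3 (permutation p = 1e-05, again the smallest possible), but a steady part of those 3 from other liver cells would give the same. Blood left in the tissue cannot be told apart either: the 4 miRNAs kept a curve after the red cell miRNAs were subtracted (0.61, permutation p = 0.00159), but the 5 preset immune miRNAs, which include miR-146a and miR-155 and lack miR-342, had 0.37 with permutation p = 0.0878, and the red cell miRNAs alone had 0.19 with permutation p = 0.401. Circulating leukocytes of mice are known to be most numerous in the light phase, so a daily change in the number or mix of leukocytes in liver blood or tissue may underlie the pattern, a hypothesis that bulk counts do not test. miR-150 and miR-142a also differed in rhythm between cortex and liver (adjusted p = 0.00426 and 0.0273, the latter 0.0705 without cortex ZT15 replicate 3), and miR-150 between hypothalamus and liver (adjusted p = 0.00157).

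In cortex 70 miRNAs were higher and 54 lower in the second passage, with miR-182, miR-183 and miR-187 among the first and miR-6240 and miR-6236 among the second. Library run as the whole cause was argued against because 81 of these kept their call with run as a term, and the libraries that stood apart because 123 kept it without them. With the log2 total as a term the ratios kept a median of 0.659 of their size, with 0.561 to 0.697 when each library was left out in turn. That range is not a confidence interval. The values argue only against a depth effect linear in the log2 total as the whole cause, and other forms were not tested. A part from depth stays open, since the median absolute ratio went from 0.24 to 0.15 with an SE of 0.07 in both fits. The 28 calls left were without miR-6240 (-1.19 ± 0.29 to -0.42 ± 0.19) and miR-6236 (-0.97 ± 0.21 to -0.35 ± 0.13), whose ratios shrank. They were also without miR-183 (0.94 ± 0.30 to 0.96 ± 0.33), whose SE grew. Other splits of the cortex libraries gave at most 2 calls. The sampling day, an age difference or handling could differ between the passages, and none was tested because the labels give no date. The animal codes were mostly lower in the first passage, so the set of animals cannot be told apart from passage. Hypothalamus and liver came largely from the same animals and had 0 calls. There 4 and 11 miRNAs had an unadjusted p under 0.05 by edgeR against 18.05 and 11.6 expected. A difference common to all tissues was thus not detected, and one limited to cortex stays open.

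Hypothalamus ZT0 replicate 9 and ZT9 replicate 8 held 111518 and 80244 CPM of miR-375, and their miR-200 family levels were also the highest of the hypothalamus, with miR-429 at 1309 and 1022 CPM against a median of 36.6. A swap with another tissue of the series was argued against by the highest miR-375 level there, 984 CPM, and an excess of 1 miRNA by the 5 miR-200 miRNAs for which these were the top libraries. The pituitary, which sits below the hypothalamus, is a candidate source: of 3 other miRNAs listed for it, at least 2 stood above the 95th percentile of the other hypothalamus libraries in both, with miR-152 at 318.4 and 296.5 CPM (median 82.6) and miR-7a-2 at 248.6 and 226.9 (median 137.1), but miR-7a-1 did not, at 56.8 and 76.2 CPM or ranks 72 and 63 of 72. The hypothalamus expresses the listed miRNAs itself at those medians, and the design gives no biological contrast for 2 single libraries. The levels of these miRNAs were thus the only check of that source. Without these and the other libraries that stood apart, 111 miRNAs in place of 113 differed between cortex and hypothalamus.

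Single libraries stood far from their group in 7 of 71 comparisons, where 3.5 would do so by chance at 1 in 20. Groups with 11 or 12 libraries, such as ZT0 to ZT12 of cortex and liver, were not screened, nor was the striatum group of 2. Cortex ZT15 replicate 1 had a total of 4238669 counts, with 2258872 next (n = 6), and striatum ZT12 replicate 1 had 3716391, with 2114804 next (n = 9). In liver miR-23b was 1069 CPM in ZT15 replicate 3 (next 824), miR-142a was 1461 in ZT18 replicate 1 (next 1172), and miR-185 was lowest in ZT18 replicate 6 at 19.04 (next 28.2). Striatum ZT21 replicate 3 held 3257 CPM of miR-195a (next 195.9, n = 5) and 4241 of miR-497a (next 269, n = 5).

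Further miRNAs were called for a difference in rhythm between tissues, and most striatum calls rest on 1 library. Striatum ZT21 replicate 3 held 4241 CPM of miR-497a and 3257 of miR-195a against medians of 176 and 135, and without it the striatum pairs with cortex, hypothalamus and liver gave 0, 0 and 1 calls in place of 2, 3 and 7. With it the adjusted p from edgeR was 5.753e-05 for both miR-195a and miR-497a against cortex, 9.449e-05 for miR-497a, 3.728e-04 for miR-195a and 0.0416 for miR-130a against hypothalamus, and 1.376e-05 for miR-497a, 2.061e-05 for miR-195a and 0.0260 for miR-194-2 against liver. Of 100 splits that reassigned the time points within each tissue, the real one included, 79 gave at least the 2 calls of cortex with striatum (highest other 35), 100 at least the 0 of cortex with hypothalamus (highest other 11), 59 at least the 3 of striatum with hypothalamus (highest other 95). With liver, 5 gave at least the 5 of cortex (highest other 17), 21 at least the 7 of striatum (highest other 44) and 73 at least the 3 of hypothalamus (highest other 11). Chance was therefore not excluded for the 5 pairs with calls, the count of 0 is reached by every split and tests nothing, and splits with many more calls than the real one point to a structure of the libraries beyond tissue and time. No split was matched to library run; with run as a term the striatum pairs with hypothalamus and liver gave 0 and 1 calls.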

How the results depend on the processing

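The fits without the 8 libraries that stood apart, the ratios of the miR-200 family and miR-183 cluster followed in the pairs of brain regions the passage fit with the log2 library total the tissue fit with library run, the animal block with CR88 read as CRM88 and rhythm differences with each library of the larger groups left out were chosen after the results were seen, and the other alternatives were planned. In the comparisons of single miRNAs with an alternative, 71 fell below the threshold, 5 rose above it and 13 reversed, and the others kept their side of it. For rhythm and tissues a reversal was not looked for where no fit called the miRNA. Nor was it looked for in rhythm fits with each library left out in turn. In liver miR-5099, miR-150, miR-223, miR-142a, miR-342, miR-16-1 and miR-29b-1 passed under each alternative with a 24 h cosine, with the largest adjusted p at 0.0262; single miRNAs were not followed with ZT as a factor or the harmonic. The liver count of 12 became 6 with ZT as a factor and 25 with a block for the title number, and ran from 7 to 14 with each library left out in turn (7 without ZT6 replicate 2). For the cortex count of 1, DESeq2 gave 8, ZT as a factor 7, the harmonic 2, the title number as a block 7, a linear time term 6, 0 to 21 h alone 6, 15 to 36 h alone 5, and the fit without the 8 libraries and with run 2. Leaving out each library gave 1 to 10, with 10 without ZT3 replicate 4 and 3 without ZT3 replicate 1, ZT3 replicate 5 or ZT6 replicate 7. For the hypothalamus count of 1, ZT as a factor gave 7, the harmonic 4, the title number as a block 61, and 0 to 21 h and 15 to 36 h alone 4 each. Leaving out each library gave 1 to 5, with 5 without ZT9 replicate 8, 4 without ZT0 replicate 9 and 2 without ZT21 replicate 3. For the striatum count of 2, library totals gave 1, no filter on low counts 4, the fit without the 8 libraries 1, and DESeq2, voom, the title number as a block, library run, 0 to 21 h alone, 15 to 36 h alone and the fit without the 8 libraries and with run 0 each. Leaving out each library gave 1 to 2, with 1 without ZT21 replicate 3, and the direction of the miR-195a curve reversed without the 8 libraries (0.11). Libraries with the same title number correlated more than others, with medians of 0.156 against -0.0204 in cortex, 0.113 against -0.0103 in striatum, 0.157 against -0.0361 in hypothalamus and 0.0348 against -0.00883 in liver, and less than libraries of a run (0.308, 0.262, 0.372 and 0.0715). Since 56.1%, 51.4%, 56.3% and 33.0% of same-number pairs, not all, had over 0.1, the numbers were not taken to pair libraries. Within each group of tissue and ZT the title number rose with the library number in the labels. It therefore followed library run in part, and a block for it takes up part of the run differences. For tissues no filter on low counts gave 85 calls for striatum with hypothalamus and 596, 606 and 616 for cortex, striatum and hypothalamus with liver, because more miRNAs were tested, and adjusted p alone gave 317, 360 and 313 in the pairs of brain regions, because the ratio minimum was dropped. Library totals in place of TMM reversed the cortex to liver ratio of miR-141 (0.0593), miR-429 (0.59), miR-183 (0.39), miR-96 (0.46), miR-145a (0.50), let-7g (1.23), let-7d (1.81), miR-30a (0.11), miR-30d (1.30), miR-30e (0.73) and miR-27b (0.59), as the median of all miRNAs moved from 1.29 to 3.07. Library run as a term, which separates liver from brain through 1 library, reversed the cortex to liver ratio of miR-375 (-6.982e-04) and left 57, 113 and 53 calls in the pairs of brain regions and 318, 328 and 324 with liver. The animal as a block changed the tissue counts by few calls, as did leaving out each library of the groups of up to 5; with CR88 read as CRM88 the block gave 52 calls in place of 55 for striatum with hypothalamus and changed no other count. For rhythm differences the animal block was fitted in limma voom, so tool and block changed together. Cortex with striatum went from 2 to 0 with the animal as a block and without the 8 libraries. Leaving out each library gave 0 to 4 (0 without striatum ZT21 replicate 3, 4 without striatum ZT18 replicate 2). Striatum with hypothalamus went from 3 to 0 with library run, with the animal as a block and without the 8 libraries, and to 1 with DESeq2; leaving out each library gave 0 to 4 (0 without striatum ZT21 replicate 3). Cortex with hypothalamus went from 0 to 3 without hypothalamus ZT0 replicate 9 and 2 without ZT9 replicate 8. Cortex with liver went from 5 to 3 with no filter and 2 with mean CPM of at least 10; leaving out each library gave 3 to 15 (3 without liver ZT6 replicate 4, 9 without liver ZT6 replicate 9 and 15 without cortex ZT3 replicate 4). Striatum with liver went from 7 to 4 with DESeq2 size factors and to 1 with library run, with the animal as a block and without the 8 libraries; leaving out each library gave 1 to 12 (1 without striatum ZT21 replicate 3, 4 without ZT0 replicate 4 or ZT21 replicate 2 and 12 without ZT12 replicate 2 or ZT21 replicate 5, all of striatum). Hypothalamus with liver went from 3 to 5 without the 8 libraries; leaving out each library gave 2 to 10 (2 without hypothalamus ZT0 replicate 12, 5 without liver ZT3 replicate 4, 7 without hypothalamus ZT0 replicate 9 and 10 without hypothalamus ZT9 replicate 8). For passages, the cortex calls became 71 with the title number as a block and 28 with the log2 total. The liver count of 0 became 1 with DESeq2 and without the 8 libraries, and leaving out each library gave 0 to 2 (2 without ZT0 replicate 5 or ZT12 replicate 8, and 1 without each of ZT0 replicate 10, ZT3 replicates 1, 6 and 10, ZT6 replicate 5, ZT9 replicates 2, 4 and 10 and ZT12 replicates 4, 6, 7 and 9). Striatum and hypothalamus gave 0 under every alternative run. The list calls for tissues went from 27 to 11 with an estimated correlation. Where no construction of the alternative is named, the cause was not tested. With many features altered at once, a simulated rhythm of ratio 1.2 was recovered for 3.03% of features in striatum. The rate was 59.4% in cortex, 44.8% in hypothalamus and 61.2% in liver. Striatum had fewer libraries (46) and a larger median SE of the ratio (0.23 against 0.11 in hypothalamus), and the part that depth had in this was not tested.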

Other observations

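The comparisons with other splits of the libraries, the test of duplicated hairpins and the choice of the libraries and markers described here came after the results were seen; the rhythm curves and tissue ratios were planned.

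Members of single families parted between brain regions. miR-34b and miR-34c, miRNAs of ciliated and p53-responding cells, were higher in hypothalamus than in cortex (log2 ratios of cortex to hypothalamus -2.01 ± 0.10 and -1.53 ± 0.11), whereas miR-34a was higher in cortex, so the list of miR-34 and miR-449 miRNAs had 2 members higher and 2 lower. The Sfmbt2 cluster miRNAs miR-467d and miR-467e, abundant in placenta, were also higher in hypothalamus (-1.14 ± 0.09 and -1.25 ± 0.09). In the Dlk1-Dio3 cluster miR-127 had -0.52 ± 0.04, below the ratio minimum, and miR-410 -0.75 ± 0.05.

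The red cell miRNAs miR-451a, miR-144, miR-486a and miR-486b had a mean curve in liver with a peak-to-trough log2 ratio of 0.19 at ZT7.98, which was not detected beyond chance (permutation p = 0.401, n = 77). Their single ratios were 0.53 ± 0.19 for miR-451a (adjusted p = 0.0630 over the list alone), 0.13 ± 0.13 for miR-144, 0.03 ± 0.15 for miR-486a and 0.40 ± 0.21 for miR-486b, so a red cell curve is not shown to be absent. miR-5099 was also tested by permutation of libraries. It gave p = 1e-05, the smallest the permutations can give, in cortex, hypothalamus and liver. It was picked because these libraries called it, so that p adds no support. In striatum, which was not used to pick it but shares animals with them, permutation gave p = 0.00110 (0.69, peak ZT9.19, adjusted p = 0.00157 over the curves tested). The edgeR test over all miRNAs gave adjusted p = 0.998 there.

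The 8 libraries that stood apart included cortex ZT0 replicate 1, ZT9 replicate 9 and ZT15 replicate 1, and liver ZT9 replicate 4. The others were hypothalamus ZT0 replicate 9 and ZT9 replicate 8, and striatum ZT9 replicate 6 and ZT21 replicate 3. Striatum ZT9 replicate 6 held 26341 counts. Striatum ZT18 replicate 1, described below, was not among the 8. Striatum ZT21 replicate 3 held, besides miR-497a and miR-195a, 4844 CPM of miR-10b (striatum median 270) and 80.5 of miR-206, a skeletal muscle miRNA (median 0.575), and little of the neuronal miR-137 (37.9, median 579) and miR-139 (97.2, median 1316). Cortex ZT0 replicate 1 held 41841 CPM of miR-204 (median 4830), 550 of miR-448 (median 37.1) and 6365 of miR-1298 (median 530). Cortex ZT15 replicate 1 held 884 CPM of miR-200a and 962 of miR-200b. Liver ZT9 replicate 4 held 6444 CPM of miR-451a (median 789), 382.3 of miR-144 (median 182.7) and 94.0 of miR-486a (median 26.7). The correlation of log2 CPM with the median profile of each tissue, taken across miRNAs, which are not independent replicates, was highest with another tissue for 4 of 273 libraries: cortex ZT0 replicate 1 (0.988 with striatum, 0.969 with cortex), cortex ZT9 replicate 9 (0.980 with striatum, 0.971 with cortex), striatum ZT21 replicate 3 (0.938 with cortex, 0.921 with striatum) and striatum ZT18 replicate 1 (0.983 with hypothalamus, 0.981 with striatum).

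Hairpins whose mature sequence is shared with another copy were compared with the others, since miR-29b-1, miR-16-1 and miR-26a-2 are of that kind. Under 100 CPM in liver 6 of 21 such hairpins (28.6%) and 26 of 123 others (21.1%) had an unadjusted p under 0.05 for rhythm, an odds ratio of 1.49 with a 95% interval from 0.429 to 4.58 (Fisher's exact p = 0.570, two-sided). The counts are too few to tell an effect of shared copies from none.

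Other splits of the libraries were drawn for the remaining counts, 100 in each case with the real one included. When the time points were reassigned within a tissue, 13 splits gave at least the 1 rhythm call of cortex (highest other 41), 22 at least the 2 of striatum (highest other 20), 67 at least the 1 of hypothalamus (highest other 26) and 1 at least the 12 of liver (highest other 2). Chance was thus argued against at 1 in 100 for the liver count and left open for the brain counts, though no split was matched to library run. This concerns the counts and does not test single miRNAs. By edgeR miR-5099, the single call of cortex and of hypothalamus, had adjusted p = 8.067e-07 and 2.268e-06. The permutation test of miR-5099 above used the same libraries that called it and adds no support there. Splits with many more calls point to a structure of the libraries. Library run itself was called for 280 of 393 miRNAs in cortex and 286 of 380 in hypothalamus, against 90 of 241 in liver. For tissues 1 split, the real one, reached the count in each pair. The highest other counts were 22 for cortex with striatum, 17 for cortex with hypothalamus and 35 for striatum with hypothalamus. With liver they were 6, 3 and 4 for cortex, striatum and hypothalamus. The labels of all 4 tissues were reassigned together, so each regrouped tissue mixed liver with brain libraries. Such mixing widens the spread within groups and lowers the counts, so these splits cannot decide about chance. For passages 1 split, the real one, reached the calls of cortex, 70 higher and 54 lower (highest other 2). This argues against chance at 1 in 100, though the splits were not matched to library run. Every one of the 100 reaches a count of 0 by construction. The splits thus test nothing for striatum (highest other 40), hypothalamus (highest other 66) and liver (highest other 1). In these tissues 47, 4 and 11 miRNAs had an unadjusted p under 0.05 by edgeR, and DESeq2 called 0, 0 and 1.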
